A study of Mus musculus with 9 samples.

How the data were processed

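The study sequenced polyA RNA from libraries labelled cholangiocyte of mice given a sham operation, bile duct ligation (BDL) or BDL plus senkyunolide A, with 3 libraries per group. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra kit. The FPKM values used here were computed by the authors and deposited as one table of 22173 gene symbols by 9 libraries. Per the submitters' processing notes, the tools were CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 and the build was GRCm38 (mm10). The order and settings of these tools, the gene annotation and the use of strand are not given in the sources used here. FPKM divide each gene's fragments by its transcript length and by the library's total, so a few very abundant genes lower the values of all others, and libraries were compared under other scalings too. The table holds 97.8% protein-coding genes by RefSeq annotation of GRCm38, and 5371 genes were listed at 0 in every library. Gene positions are from that annotation, counted from 1.

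Library groups were taken from the sample labels, and column names matched the sample titles. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. No pair of libraries held identical values: within groups the correlation of log2(FPKM + 1) was 0.972 to 0.993 in sham, 0.940 to 0.968 in BDL and 0.921 to 0.989 in BDL plus senkyunolide A, and no library was merged or left out.

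Depth was estimated from the deposited FPKM. Relative depth was the most common ratio of values between libraries among genes with a mean FPKM under 0.3 (189 to 225 genes per library). As a check at this depth, 78.6% of 17202 low values were whole multiples of one step per fragment. The check allowed values within 0.02 of a step and up to 20 fragments. Genes with a single transcript gave the absolute scale. The estimate was 27.3 to 33.8 M (mega) fragments per library. Counts were not recovered, so no count model was used and no counting interval is given.

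Values were analysed as log2(FPKM + 1), and a fold change on this scale understates the change of genes of low level. The 9884 genes with a mean FPKM of at least 1 over the 9 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model over all 3 groups, empirical Bayes with a variance trend, two-sided). Calls were made at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were BDL against sham, BDL plus senkyunolide A against BDL, BDL plus senkyunolide A against sham, and genes called in opposite directions by the first and second. For the last, which share libraries, 100 simulations of unchanged groups gave the value without effects.

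The designs, 31 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The lists cover biliary epithelium, hepatocytes, macrophages, neutrophils, lymphocytes, endothelium, stellate cells and fibroblasts, erythroid and mesothelial cells, and pathways that fit cholestasis and the series title. Of these 29 had at least 5 tested members and were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The list of 3 title genes was read gene by gene. Some lists share members, such as Dcn and Lum in the stellate and matrix lists and Icam1 and Cxcl1 in the NF-kappaB and reactive secretory lists. Counts of called lists are therefore not counts of independent results. The list of mitochondrially encoded genes had 0 members in the table and was not analysed here. Camera compares a list with all other genes, whereas fry asks whether its genes move, on balance, one way.

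Named genes were Myc, Traf6 and Hdac3, and per comparison the 8 largest rises and 8 largest falls among protein-coding genes that passed without overlap between the groups. Where none passed in a direction, the 4 with the smallest p were given as values. Up to 4 members of each described list with the smallest p were named, and the 5 strongest genes called in opposite directions, of which there was 1. Some genes that the rule takes in are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

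The procedure was tested on simulated data made from the 9884 genes, with 200 genes changed per comparison. Noise was drawn independently for each gene, whereas in the real libraries the estimated correlation between genes of a list was 0.065 to 0.74. The count of unchanged lists called below therefore does not measure how often lists are called falsely in the real data. At a log2 change of 1 it recovered 47% in BDL against sham, 55% in BDL plus senkyunolide A against BDL and 54% in BDL plus senkyunolide A against sham, and at a log2 change of 2 it recovered 96%, 95% and 97%, with 8, 5 and 6 false calls and 0 unchanged lists called.

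The other settings were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, TPM rescaling, no variance trend, robust empirical Bayes, array weights, the 6 libraries of the groups compared alone, the replicate number as a block, a log2 fold limit of 1, and each library left out in turn with the filter recomputed. Log2 changes correlated with transcript length across genes (Spearman -0.165, -0.227 and -0.346 in the 3 comparisons, over the 98.6% of tested genes with a length), so removal of the length trend within each library was added after the data were seen. Depth and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.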

Results

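Gene expression was measured by polyA RNA sequencing in mouse libraries labelled cholangiocyte, the epithelial cell that lines the bile ducts. The mice had a sham operation, bile duct ligation (BDL), which blocks bile flow and causes cholestasis, or BDL plus senkyunolide A, a small phthalide found in the herb Ligusticum chuanxiong. Each of the 3 groups had 3 libraries, 9 in all. The values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 22173 genes. Of these, 9884 had a mean FPKM of at least 1 and were tested. The estimated depth, in M (mega) fragments, was 30.9, 28.6 and 27.3 M in the sham libraries and 33.8, 32.2 and 31.8 M in the BDL libraries. It was 30.7, 33 and 32.5 M in the BDL plus senkyunolide A libraries. The series title names TRAF6, HDAC3 and c-MYC, so the genes Traf6, Hdac3 and Myc were read in every comparison.

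Hepatocyte transcripts led in every library. Albumin (Alb), the main plasma protein made by hepatocytes, had the highest FPKM of all genes in 8 of the 9 libraries and the second highest in BDL plus senkyunolide A library 2. It read 38130 ± 8630 FPKM in sham, 30485 ± 8038 in BDL and 29029 ± 6636 in BDL plus senkyunolide A (SD, n = 3). The 36 hepatocyte markers took 29.2% ± 2.91 of the summed FPKM in sham, 22.4% ± 2.8 in BDL and 24% ± 3.93 in BDL plus senkyunolide A (SD, n = 3). The 34 biliary epithelial markers took 0.0727% ± 0.0177, 0.337% ± 0.117 and 0.223% ± 0.0896 (SD, n = 3). Both shares separated the sham from the BDL libraries without overlap, which in an exact two-sided permutation test of 3 against 3 gives p = 0.1, the smallest it allows. How the cells were isolated is not given in the sources used here.

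**Figure D1:**
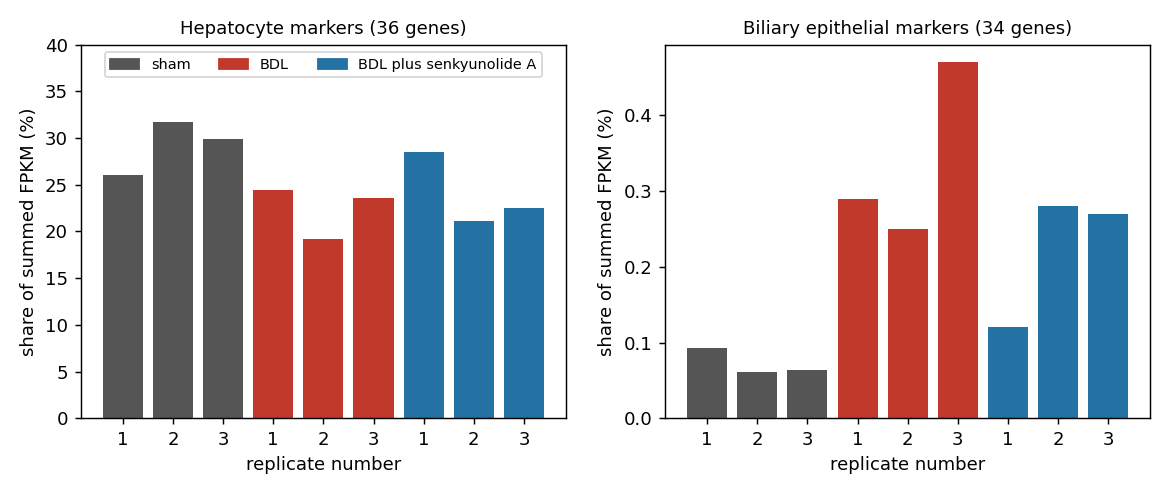
Share of the summed FPKM (%, bars from 0) taken by 36 hepatocyte markers (left) and 34 biliary epithelial markers (right) in each of the 9 libraries, coloured by group. The hepatocyte share lies between 19.2% and 31.7% and the biliary share between 0.061% and 0.47%, on axes of different scale.

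BDL plus senkyunolide A library 1 stood apart from libraries 2 and 3 of its group. On the first principal component of the tested genes, which held 53.8% of the variance, it lay at -16.9, and libraries 2 and 3 of its group at 26.7 or above. The sham libraries lay between -49.6 and -37.5 and the BDL libraries between 14.7 and 40.1. Lcn2, which encodes the secreted iron-siderophore binding protein lipocalin 2, read 169 FPKM there, against 5902 and 8086 in libraries 2 and 3 and 2.85 to 14.7 in sham. Hsd3b5, a steroid-metabolizing enzyme of the male mouse liver, read 225 FPKM there, against 0.302 and 0.134 in libraries 2 and 3 and 241 to 301 in sham. Mup17, a major urinary protein gene, read 440 FPKM there against 20.9 and 11, and the macrophage receptor gene Marco 10.9 FPKM against 95.6 and 96.4. Its hepatocyte share was 28.5%, against 21.1% and 22.5% in libraries 2 and 3.

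**Figure D2:**
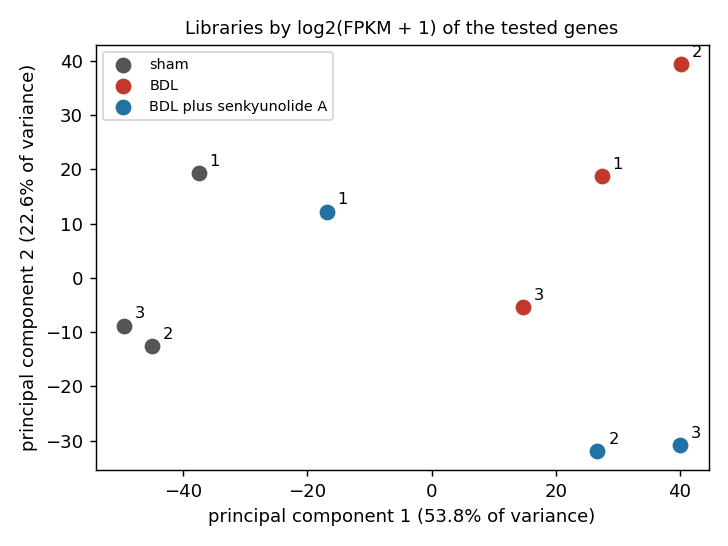
Principal components 1 and 2 (53.8% and 22.6% of the variance, no unit) of log2(FPKM + 1) over the tested genes; each point is a library, coloured by group and numbered by replicate. BDL plus senkyunolide A library 1 lies at -16.9 on component 1, between the sham libraries and the other 5.

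The first comparison, BDL against sham, addressed what ligation of the bile duct did to these libraries. Lcn2 rose from 7.59 ± 6.29 to 1183 ± 551 FPKM (SD, n = 3), a log2 change of 7.22 ± 1.18 (SE). The metal-binding metallothioneins Mt2 and Mt1 rose by 7.17 ± 0.94 and 6.36 ± 0.92. The acute phase plasma protein gene Orm2 rose by 5.91 ± 1.04, and the glutathione transferases Gstm3 and Gsta1 by 5.23 ± 0.37 and 4.48 ± 0.61. The steepest falls were in liver genes. Hsd3b5 fell from 267 ± 30.5 to 1.86 ± 0.786 FPKM, a log2 change of -6.58 ± 1.52. The major urinary protein gene Mup7 fell from 10067 ± 3870 to 308 ± 438 FPKM, a log2 change of -6.28 ± 1.57. The keratins Krt18 and Krt8 of simple epithelia and Krt7 of the biliary epithelium rose by 2.86 ± 0.31, 2.50 ± 0.34 and 1.56 ± 0.24.

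In limma with Benjamini-Hochberg adjustment, 1084 of the 9884 genes passed, 803 higher and 281 lower in BDL, and 811 of them changed by at least 1 on the log2 scale. At an unadjusted p under 0.05 there were 2826 genes, and in 30.5% of genes the 2 groups did not overlap. The mean over all splits is 10%, which genes that vary together can exceed. The count fell to 172 without sham 2, 151 without sham 3, 181 without BDL 2 and 720 without BDL 1. It was 1763 without BDL plus senkyunolide A library 1, which is in neither of the groups compared. The deposited scaling put the median log2 change of all genes at 0.152. Median-ratio scaling moved it to -0.001 and the split to 545 higher and 468 lower, and quantile normalization moved it to -0.033 and the split to 452 higher and 473 lower. Among the 58 genes named for this comparison 55 passed. With each library left out in turn 19 of these passed throughout, which include Lcn2, Mt1, Mt2, Orm2, Gstm3, Gsta1, Krt18, Krt8 and Krt7. Another large rise was in Cib3 (4.58 ± 0.64), a calcium and integrin binding family member. Other large falls were in Mup11, Mup15 and Mup17 (-6.41 to -6.30) and the sulfotransferase Sult2a8 (-6.14 ± 1.57), and in the carbonic anhydrase Car3 (-5.90 ± 1.42) and the fatty acid elongase Elovl3 (-5.84 ± 1.46). Each of the 8 largest falls lost its call without sham 2, sham 3 or BDL 2, and Hsd3b5, Mup7, Sult2a8, Car3 and Elovl3 also without sham 1 or BDL 1 and Mup11 without BDL 1. The log2 changes of these 8 genes stayed between -7.75 (Mup7) and -4.99 (Elovl3) over 21 alternatives. Members of the Mup, Gstm, Gsta, Orm, Serpina1 and Serpina3 families are near-identical in sequence, so reads may have been divided between them and single-gene values are uncertain.

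Markers of macrophages and monocytes rose most broadly of the cell type lists: 16 of 29 rose and none fell, and 24 rose when adjusted over the list alone. The median log2 change was 1.60. Marco, a scavenger receptor of Kupffer cells, rose by 3.76 ± 0.64, from 2.69 ± 0.405 to 49.7 ± 11.5 FPKM, and Cd68, a lysosomal protein of macrophages, by 1.72 ± 0.34. Camera called the list higher (limma, adjusted p = 3.89e-08; adjusted p = 0.64 with an estimated correlation). Of 7 neutrophil markers 3 rose (5 rose and 1 fell adjusted over the list alone), with S100a8 at 3.06 ± 0.60 and S100a9 at 2.84 ± 0.52, subunits of calprotectin. Its camera adjusted p was 0.0442, and adjusted p = 0.69 with an estimated correlation. Of 9 lymphocyte markers 4 rose (7 adjusted over the list alone), among them the class II invariant chain Cd74 (2.08 ± 0.36) and the immunoglobulin joining chain Jchain (2.22 ± 0.40). Its camera adjusted p was 0.00262, and adjusted p = 0.64 with an estimated correlation. The neutrophil call ended without sham 1, BDL 1, BDL 3 or BDL plus senkyunolide A library 3 (adjusted p 0.00403 to 0.199 over 13 other settings). The lymphocyte call ended without BDL 3 (0.000492 to 0.0754).

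Part of the biliary epithelial, acute phase, NF-kappaB and reactive secretory lists rose as well. Of 20 tested biliary epithelial markers 8 rose and 1 fell (10 and 1 adjusted over the list alone). The list had a median of 0.99 and a camera adjusted p of 0.00112 (adjusted p = 0.64 with an estimated correlation). The one that fell was Onecut1 (-1.68 ± 0.33), a liver and bile duct transcription factor also made by hepatocytes. The biliary share of summed FPKM was higher in the same libraries, as given above. Krt18 and Krt8, keratins of simple epithelia in general, entered it with 77.4 and 92.5 FPKM in sham and 564 and 541 in BDL. Krt7 entered it with 0.334 and 2.95 FPKM. The higher share therefore need not mean more biliary epithelium. Of 26 acute phase genes 10 rose (12 adjusted over the list alone). The list had a median of 1.63 and a camera adjusted p of 4.09e-05 (adjusted p = 0.64 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, rose by 2.09 ± 0.33 and Lrg1, a secreted leucine-rich glycoprotein, by 2.64 ± 0.44. Of 28 NF-kappaB target genes 9 rose (14 rose and 1 fell adjusted over the list alone). Camera gave an adjusted p of 0.000106, and adjusted p = 0.64 with an estimated correlation. Rises were seen in the adhesion molecule Icam1 (1.88 ± 0.36) and the NF-kappaB inhibitor Tnip1 (1.08 ± 0.20). Of 18 reactive cholangiocyte secretory genes 5 rose (9 adjusted over the list alone; camera adjusted p = 0.0108, and adjusted p = 0.75 with an estimated correlation). This call ended without sham 1 or BDL 3 (adjusted p 0.000128 to 0.104 over 13 other settings).

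Part of the NRF2, cholesterol synthesis, senescence and ribosomal lists rose too. Of 29 NRF2 and glutathione genes 13 rose and none fell (16 and 1 adjusted over the list alone). The list had a median of 0.88 and a camera adjusted p of 3.05e-05 (adjusted p = 0.64 with an estimated correlation). Gpx2, a glutathione peroxidase of epithelia, rose by 3.40 ± 0.22, from 0, 0 and 0.0343 FPKM in the sham libraries to 9.76 ± 1.68 in BDL, and Gsta2 and Gstm2 rose by 2.97 ± 0.35 and 1.97 ± 0.24. Of 24 cholesterol synthesis genes 10 rose (15 adjusted over the list alone). The list had a median of 1.03 and a camera adjusted p of 8.14e-05 (adjusted p = 0.64 with an estimated correlation). Mvd, which encodes mevalonate diphosphate decarboxylase, rose from 6.36 ± 5.71 to 34.1 ± 13.2 FPKM (log2 change 2.46 ± 0.46). Of 25 senescence and p53 target genes 7 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.00257, and adjusted p = 0.64 with an estimated correlation). There were rises of 1.99 ± 0.36 in Phlda3 and 1.89 ± 0.35 in Btg2 and a fall of -1.60 ± 0.32 in Igfbp3, a binding protein of insulin-like growth factors. All 48 cytosolic ribosomal protein genes had positive values, and 5 rose (19 adjusted over the list alone). The median was 0.61 (camera adjusted p = 5.6e-08; adjusted p = 0.64 with an estimated correlation), and Rps20 and Rps19 rose by 1.06 ± 0.23 and 0.98 ± 0.23.

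Falls were seen among hepatocyte markers. Of 36 markers 8 fell and 1 rose (13 and 3 adjusted over the list alone). The list had a median of -0.40 and a camera adjusted p of 2.79e-05 (adjusted p = 0.64 with an estimated correlation). The protease inhibitors Serpina3k and Serpina1d fell by 1.98 ± 0.42 and 1.27 ± 0.27 on the log2 scale, while transferrin (Trf) rose by 1.37 ± 0.30. Quantile normalization ended the list call (adjusted p 1.79e-06 to 0.0973 over 13 other settings). Of 31 bile acid synthesis and transport genes 4 rose and 6 fell (4 and 9 adjusted over the list alone; median -0.10, mean -0.47). Camera gave an adjusted p of 0.0181, and adjusted p = 0.64 with an estimated correlation. Cyp7b1, an oxysterol hydroxylase, fell by 3.24 ± 0.66, whereas the export transporter genes Slc51b and Abcb1a rose by 2.70 ± 0.63 and 1.88 ± 0.28. Camera also called 3 further lists lower, and 0 of them with an estimated correlation (adjusted p = 0.75, 0.75 and 0.83 in the order below). Of these the endothelial cell markers had a median of -0.21 and an adjusted p of 0.00299 (0 of 26 passed in limma, 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone). The oxidative phosphorylation genes had a median of -0.06 and an adjusted p of 0.00685 (0 of 38 passed in limma, 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone). The interferon response genes had a median of -0.10 and an adjusted p of 0.0425 (1 of 29 fell and 0 adjusted over the list alone). The endothelial call ended without BDL 1 (2.44e-06 to 0.544 over 13 other settings). The median FPKM of all listed endothelial markers was 2.36, 4.51 and 7.47 in BDL 1, 2 and 3 against 6.68, 5.04 and 3.67 in sham. BDL 3 thus lay above every sham library. The oxidative phosphorylation call ended without BDL 1 or sham 2 and with quantile normalization (4.8e-05 to 0.192). The interferon call ended without BDL 1, BDL 2, sham 2 or BDL plus senkyunolide A library 1, with median-ratio and quantile scaling and with length correction (0.000762 to 0.22). The bile acid call ended without BDL 3 and under the same 3 settings (0.00368 to 0.242).

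Of the genes in the series title none passed in BDL against sham. Myc, the proto-oncogene on chromosome 15 (61985341 to 61990361, GRCm38), read 5.31 ± 3.94 FPKM in sham and 8.82 ± 2.98 in BDL (SD, n = 3). The log2 difference was 0.83 with a 95% interval from -0.16 to 1.81 (limma adjusted p = 0.251). Traf6, a ubiquitin ligase of Toll-like receptor signalling on chromosome 2 (101678420 to 101701668), differed by -0.28 ± 0.20 (adjusted p = 0.389), and Hdac3, a histone deacetylase on chromosome 18 (37936971 to 37955015), by 0.27 ± 0.19 (adjusted p = 0.384). Benjamini-Hochberg adjusted over the list alone, the limma adjusted p of each of the 3 was 0.186. Of 47 MYC target genes 1 rose, Ung (0.87 ± 0.17), with 1 adjusted over the list alone, and the list was not called (median 0.22, camera adjusted p = 0.799). Of 15 histone deacetylase family genes 0 passed in limma, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median 0.16, camera direction down, adjusted p = 0.872). Of 25 TRAF6 and Toll-like receptor pathway genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; median 0.29, camera adjusted p = 0.872).

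Camera calls compared each list with all other genes. In BDL against sham 16 of 29 lists were called, 11 higher and 5 lower. Of these 8 were called under all 13 other settings of scaling, length correction and left-out library. These were the biliary epithelial, NF-kappaB, senescence and p53, NRF2, cholesterol, acute phase, macrophage and ribosomal lists. With an estimated correlation camera called 0 of the 29 lists (adjusted p 0.64 to 0.97), and fry called 7. The fry calls were the biliary epithelial, senescence and p53, NRF2, cholesterol, ribosomal, lymphocyte, and immediate early and heat shock lists. Fry did not call the macrophage (fry adjusted p = 0.0669), NF-kappaB (0.0717) and acute phase lists (0.0852).

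**Figure D3:**
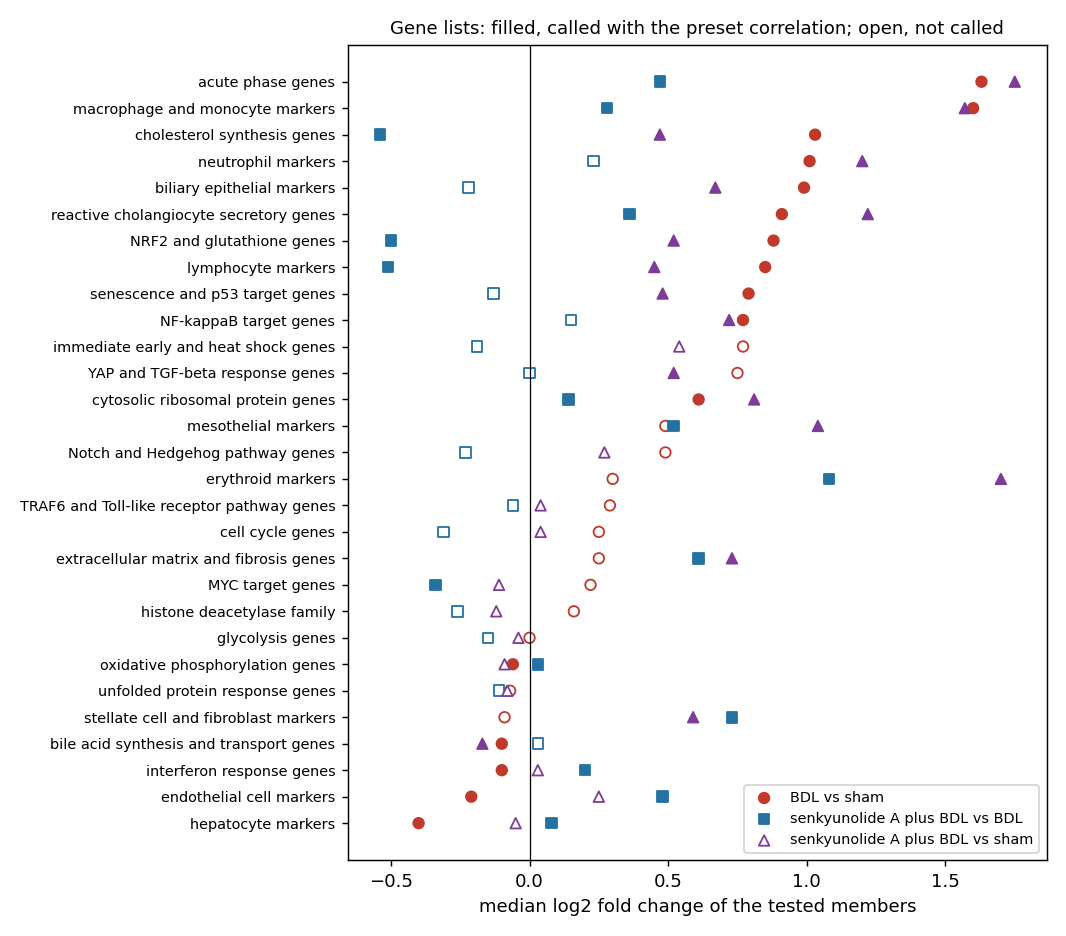
Median log2 fold change of the tested members (horizontal axis, log2 units) of each of 29 gene lists in the 3 comparisons, by colour and shape; filled points were called by camera with the preset correlation. Medians of the cholesterol and NRF2 lists lie above 0 in BDL against sham (1.03 and 0.88) and below 0 in BDL plus senkyunolide A against BDL (-0.54 and -0.50). These comparisons share the BDL libraries, which alone gave opposite signs in 66.7% of genes in simulations. The opposite signs of list medians were not tested against this.

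The second comparison, BDL plus senkyunolide A against BDL, addressed what the compound changed in ligated mice. Gstm3, a glutathione transferase on chromosome 3 (107963696 to 107969174), fell from 1486 ± 698 to 158 ± 47.8 FPKM (SD, n = 3), a log2 change of -3.15 ± 0.37 (SE). It was the one gene of 9884 that passed (limma, Benjamini-Hochberg adjusted p = 0.0285), and all 3 libraries lay below all 3 BDL libraries. Gstm1, another glutathione transferase, read 5211 ± 1685 FPKM in BDL and 1068 ± 614 with senkyunolide A (log2 difference -2.37 ± 0.41), and Gpx2 read 9.76 ± 1.68 and 3.32 ± 1.05 (-1.33 ± 0.22). Neither passed in limma (adjusted p = 0.242 and 0.203; over 21 and 20 alternatives 0.00131 to 0.778 and 0.00202 to 0.778). At an unadjusted p under 0.05 there were 1212 genes, and in 17.6% of genes the groups did not overlap, against a mean of 10% over all splits. Genes vary together, so a split can exceed this mean without an effect of the compound. Another split of these 6 libraries gave 327 called genes, against 1 for the real split.

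The single call depended on which libraries entered. Gstm3 passed in 12 of 21 alternatives, with log2 changes of -3.57 to -2.80 and adjusted p from 0.00112 to 0.458. It passed without BDL 1, BDL 3 or BDL plus senkyunolide A library 1 (adjusted p 0.00353, 0.0089 and 0.00557). Without any 1 of the other 6 libraries its adjusted p was 0.0763 to 0.221. The count of genes was 64 without BDL plus senkyunolide A library 1, 62 without BDL 3, 1 without BDL 1 and 0 without each of the others. The deposited scaling put the median log2 difference of all genes at -0.116, median-ratio scaling at -0.005 and TPM rescaling at -0.261, and Gstm3 was the one call under each.

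Of 29 NRF2 and glutathione genes 1 fell, Gstm3, and 9 fell when adjusted over the list alone. The median was -0.50, camera called the list lower (adjusted p = 0.00107), and adjusted p = 0.73 with an estimated correlation. Gsta2 read 183 ± 45.7 FPKM in BDL and 79 ± 34.5 with senkyunolide A (log2 difference -1.27 ± 0.35). A further 4 lists, of non-epithelial cells and matrix, were called higher, and 0 of them with an estimated correlation. These and the NRF2 list were called under all 13 other settings of scaling, length correction and left-out library. The stellate and matrix lists share members, Dcn and Lum among them, so their calls are not independent. Of 26 endothelial cell markers 25 had positive values (median 0.48, adjusted p = 2.46e-08; adjusted p = 0.78 with an estimated correlation), with Clec4g, a lectin of sinusoidal endothelium, at 1.28 ± 0.39 and Fcgr2b, an Fc receptor of the same cells, at 1.30 ± 0.44. Of 19 stellate cell and fibroblast markers 17 had positive values (median 0.73, adjusted p = 5.6e-08; adjusted p = 0.73 with an estimated correlation), with the matrix proteoglycans Dcn at 1.78 ± 0.49 and Lum at 1.94 ± 0.58. In 23 extracellular matrix and fibrosis genes the median was 0.61 (adjusted p = 1.43e-07; adjusted p = 0.73 with an estimated correlation), with the fibril-associated collagen Col14a1 at 1.36 ± 0.37. In the endothelial, stellate and matrix lists BDL 3 stood apart from BDL 1 and 2. The median FPKM of all listed stellate markers was 0.512 and 0.816 in BDL 1 and 2 but 2.9 in BDL 3, against 2.2, 2.66 and 1.48 with senkyunolide A. That of the endothelial markers was 2.36, 4.51 and 7.47 in BDL against 5.42, 6.93 and 5.66, and Fcgr2b read 14.2, 13.1 and 47.9 FPKM against 33.9, 77.8 and 56.5. In the matrix list Dcn read 12.5, 16.7 and 59.5 FPKM in BDL against 72.1, 127 and 61.1, and Col14a1 0.7, 1.09 and 3.77 against 6.65, 6.84 and 3.77. In the erythroid list Hbb-bs read 66.8, 92.1 and 237 against 312, 528 and 321, whereas the median of all its listed markers was lowest in BDL 3 (2.1, 2.66 and 1.08 FPKM against 1.57, 2.86 and 1.49). BDL 3 correlated at 0.972 with BDL plus senkyunolide A library 2, above its 0.953 and 0.940 with BDL 1 and 2. The median differences of the endothelial, stellate, matrix and erythroid lists were 0.80, 1.21, 0.97 and 1.45 without BDL 3. Without BDL 1 they were 0.13, 0.47, 0.27 and 0.97, so the size of the difference depended on which BDL libraries entered. The share of hepatocyte transcripts was 22.4% and 24% in the 2 groups, as given above. In 7 erythroid markers the median was 1.08 (adjusted p = 1.46e-05; adjusted p = 0.73 with an estimated correlation), with the globins Hbb-bs at 1.72 ± 0.41 and Hba-a1 at 1.08 ± 0.34. In these 4 lists 0 members passed over all genes in limma, with 4, 9, 8 and 5 members at an unadjusted p under 0.05 and 0, 0, 3 and 4 higher when adjusted over the list alone.

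Cholesterol synthesis and MYC target genes were called lower with calls that single libraries ended. Of 24 cholesterol synthesis genes 0 passed in limma, 9 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (median -0.54, camera adjusted p = 0.00754; adjusted p = 0.81 with an estimated correlation). Mvd read 34.1 ± 13.2 FPKM in BDL and 12.8 ± 3.48 with senkyunolide A (-1.31 ± 0.46), and Dhcr7 40.7 ± 6.27 and 20.5 ± 5.6 (-0.98 ± 0.32). Of 47 MYC target genes 0 passed in limma, 12 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (median -0.34, camera adjusted p = 0.0253; adjusted p = 0.81 with an estimated correlation). Among them the nucleolar protein Ncl differed by -0.83 ± 0.21, the importin Ipo4 by -0.91 ± 0.31 and the nucleolar Mybbp1a by -0.87 ± 0.31, while Ldha, which makes lactate, had a positive value of 0.78 ± 0.28. The cholesterol call ended without BDL plus senkyunolide A libraries 1 or 3 or BDL 1 (adjusted p 5.63e-06 to 0.0877 over 13 other settings). The MYC target call ended without BDL plus senkyunolide A libraries 2 or 3 or BDL 3 (0.00919 to 0.134).

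Of the title genes none passed in this comparison. Myc read 8.82 ± 2.98 FPKM in BDL and 4.95 ± 1.43 with senkyunolide A (SD, n = 3). The log2 difference was -0.70 with a 95% interval from -1.69 to 0.28 (limma adjusted p = 0.482, and over 21 alternatives from 0.0376 with array weights, where it passed, to 0.785). Traf6 differed by 0.01 ± 0.20 (adjusted p = 0.987) and Hdac3 by -0.10 ± 0.19 (adjusted p = 0.799), both of which took the other sign under some alternatives. Adjusted over the list alone the 3 p-values in limma were 0.434, 0.964 and 0.899. Of 15 histone deacetylase family genes 0 passed in limma, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median -0.26, camera adjusted p = 0.334). Of 25 TRAF6 and Toll-like receptor pathway genes 0 passed in limma, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median -0.06, camera adjusted p = 0.658).

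**Figure D4:**
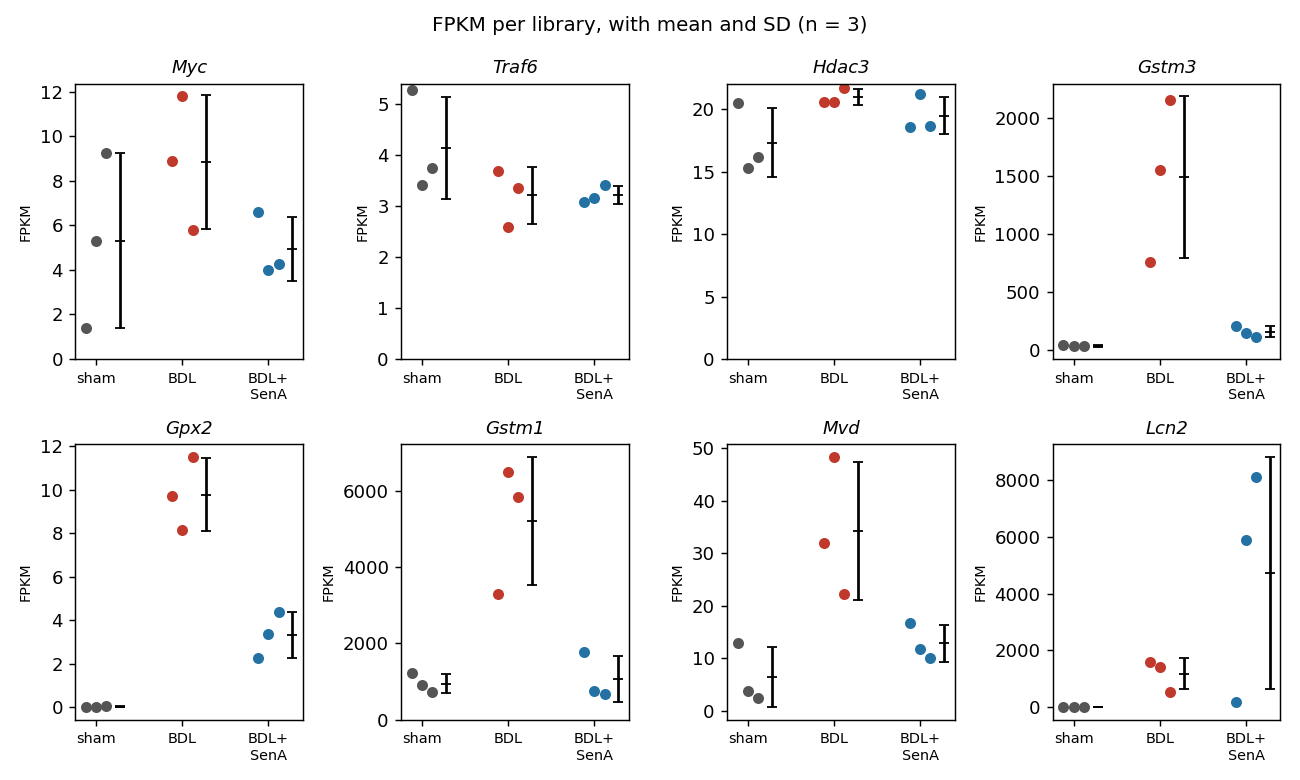
FPKM of 8 genes in each library (points, coloured by group: sham, BDL, and BDL plus senkyunolide A written as BDL+SenA), with the group mean and SD (bars, n = 3); vertical axes are linear and differ between genes. Gstm3 lies at 116 to 210 with senkyunolide A against 761 to 2153 in BDL, whereas Myc overlaps between groups.

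In this comparison 16 of 29 lists were called by camera, 12 higher and 4 lower, and 5 of these under all 13 other settings of scaling, length correction and left-out library. The count was 10 without BDL 3 and 10 without BDL plus senkyunolide A library 3. With an estimated correlation camera called 0 of the 29 lists (adjusted p 0.73 to 0.89), and fry called 0. None of the positive differences passed in limma. Those with the smallest p were in Cyp4b1 (1.21 ± 0.23), a cytochrome P450, the serpins Serpina3f (1.38 ± 0.29) and Serpina3g (1.73 ± 0.38), and the mannose-binding lectin Mbl1 (1.18 ± 0.26).

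The third comparison, BDL plus senkyunolide A against sham, addressed how far ligated mice given the compound differed from unligated ones. Lcn2 rose by 8.12 ± 1.18 (SE), from 7.59 ± 6.29 to 4719 ± 4089 FPKM (SD, n = 3), and Mt2, Mt1 and Orm2 rose by 7.47 ± 0.94, 6.28 ± 0.92 and 6.26 ± 1.04. Spink1, a secreted trypsin inhibitor, rose by 4.37 ± 0.60 and Cib3 by 4.34 ± 0.64. Rises were also found in the acute phase gene Orm3 (4.21 ± 0.86) and in Cd14 (4.12 ± 0.77), a co-receptor for lipopolysaccharide. BDL plus senkyunolide A library 1 lay far below libraries 2 and 3 in several of these genes. Orm2 read 67.3 FPKM there against 2263 and 2194, and Cd14 6.5 against 78.5 and 115. Over 21 alternatives the log2 change of Orm2 was 5.41 to 7.93 and that of Cd14 3.37 to 5.35. Among protein-coding genes that passed without overlap, the steepest falls were in Mup17, Mup21 and Mup9 (-5.50 to -4.36). Acsl1 (-2.47 ± 0.52), an acyl-CoA synthetase, came next. This ranking leaves out genes that did not pass. One is Hsd3b5, which read 225, 0.302 and 0.134 FPKM against 241 to 301 in sham. Falls were also found in Slc25a30 (-2.19 ± 0.32), a mitochondrial carrier, Slc17a8 (-2.14 ± 0.35), a glutamate transporter, Lifr (-1.96 ± 0.40), a cytokine receptor, and Onecut1 (-1.91 ± 0.33).

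In limma with Benjamini-Hochberg adjustment 214 of 9884 genes passed, 174 higher and 40 lower, and 2294 had an unadjusted p under 0.05. In 29.6% of genes the groups did not overlap, against a mean of 10% over all splits, which genes that vary together can exceed. The count was 0 without sham 1, sham 3 or BDL plus senkyunolide A library 2, 1 without sham 2 and 7 without BDL plus senkyunolide A library 3. It was 325 without BDL 3 and 1837 without BDL plus senkyunolide A library 1. Of the 36 genes named here 33 passed and 0 of them did so with each library left out in turn. The median log2 difference of all genes was 0.036, which TPM rescaling moved to -0.066. Quantile normalization gave 28 higher and 14 lower genes.

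Of 29 macrophage and monocyte markers 7 rose (26 adjusted over the list alone; median 1.57, camera adjusted p = 6.43e-15, and adjusted p = 0.46 with an estimated correlation). Marco rose by 3.71 ± 0.64 and the lipid receptor Trem2 by 2.96 ± 0.58. The Marco value of BDL plus senkyunolide A library 1 was the lowest of its group, as given above. Of 7 neutrophil markers 3 rose (5 adjusted over the list alone; median above 1, camera adjusted p = 0.00115, and adjusted p = 0.46 with an estimated correlation). S100a8 rose by 3.31 ± 0.60 and S100a9 by 3.06 ± 0.52. Of 26 acute phase genes 5 rose (18 adjusted over the list alone; median 1.75, camera adjusted p = 2.31e-11, and adjusted p = 0.46 with an estimated correlation). Socs3 rose by 2.55 ± 0.33. Of 18 reactive cholangiocyte secretory genes 4 rose (13 adjusted over the list alone; median 1.22, camera adjusted p = 4.95e-07, and adjusted p = 0.46 with an estimated correlation), with the chemokine Cxcl1 at 4.01 ± 0.78. Of 20 biliary epithelial markers 3 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.67, camera adjusted p = 0.00167, and adjusted p = 0.51 with an estimated correlation). Krt18 rose by 2.05 ± 0.31 and Krt7 by 1.35 ± 0.24. Of 29 NRF2 and glutathione genes 7 rose (10 rose and 3 fell adjusted over the list alone; median 0.52, camera adjusted p = 0.00104, and adjusted p = 0.46 with an estimated correlation). Gpx2 rose by 2.07 ± 0.22 and Gstm3 by 2.08 ± 0.37.

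Of 48 cytosolic ribosomal protein genes 8 rose (37 adjusted over the list alone; median 0.81, camera adjusted p = 5.9e-16, and adjusted p = 0.46 with an estimated correlation). Rpl32 rose by 1.31 ± 0.24 and Rps20 by 1.21 ± 0.23. Of 7 erythroid markers 2 rose (5 adjusted over the list alone; median 1.70, camera adjusted p = 0.00666, and adjusted p = 0.46 with an estimated correlation), Hba-a1 (1.70 ± 0.34) and Hbb-bs (1.77 ± 0.41); the call ended without BDL plus senkyunolide A library 1 (adjusted p 0.000209 to 0.0575 over 13 other settings). Of 23 extracellular matrix and fibrosis genes 1 rose, the metalloproteinase inhibitor Timp1 (3.12 ± 0.59), with 10 adjusted over the list alone (median 0.73, camera adjusted p = 0.000209, and adjusted p = 0.54 with an estimated correlation). Of 28 NF-kappaB target genes 3 rose, the BCL2 family gene Bcl2a1d (1.32 ± 0.18), which has near-identical paralogs, Cxcl1 and Icam1 (1.61 ± 0.36), with 13 adjusted over the list alone (median 0.72, camera adjusted p = 1.04e-08, and adjusted p = 0.46 with an estimated correlation). In 7 further called lists 0 members passed over all genes in limma, and 0 of these lists were called with an estimated correlation (adjusted p 0.51 to 0.64). Higher were the senescence and p53 (median 0.48, adjusted p = 0.00144), YAP and TGF-beta (0.52, 0.00558), cholesterol (0.47, 0.00903), stellate (0.59, 0.00903), lymphocyte (0.45, 0.0279) and mesothelial lists (1.04, 0.0387). The bile acid list was lower (-0.17, 0.0342). The senescence and YAP calls held under the 13 other settings, and the other 5 ended under some. The cholesterol call ended without BDL plus senkyunolide A library 2 or sham 3 (adjusted p 0.000209 to 0.068 over 13 other settings), and the stellate call without library 2 or sham 1 (0.000256 to 0.0955). The lymphocyte call ended without library 1 or sham 3, with quantile normalization and with length correction (0.00207 to 0.241). The mesothelial call ended without library 2, BDL 2 or sham 1 and with length correction (0.0178 to 0.154), and the bile acid call with median-ratio and quantile scaling (0.0217 to 0.0595). In these 7 lists 10, 9, 8, 8, 4, 4 and 13 members had an unadjusted p under 0.05, in the order given. Adjusted over each list alone 9, 7, 0, 7, 1, 3 and 2 were higher, and 1 YAP and TGF-beta gene and 5 bile acid genes were lower. Camera called 17 of 29 lists, 16 higher and 1 lower, and 11 of them under all 13 other settings of scaling, length correction and left-out library. It called 0 with an estimated correlation (adjusted p 0.46 to 0.97) and 1 with fry. The title genes did not pass in limma: Myc differed by 0.12 ± 0.45 (adjusted p = 0.907), Traf6 by -0.27 ± 0.20 (adjusted p = 0.452) and Hdac3 by 0.17 ± 0.19 (adjusted p = 0.654), with p-values from 0.595 to 0.788 adjusted over the list alone. With array weights Myc took the other sign and passed (-0.78, adjusted p = 0.0063; 0.0063 to 0.996 over 21 alternatives). Hdac3 passed there too (0.34, adjusted p = 0.00627; 0.00627 to 0.913).

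Genes that moved one way with ligation and the other way with senkyunolide A were counted across the first and second comparisons, which share the BDL libraries. Gstm3 was the one gene called in both with opposite signs, rising by 5.23 ± 0.37 and falling by 3.15 ± 0.37 in limma. Simulated unchanged groups gave 0 such genes in 100 draws, and independent lists of these sizes would share 0.081. Without effects almost no gene is called in either comparison, so the simulated 0 was fixed beforehand and does not test a reversal. Of 100 drawn splits of the 9 real libraries 7, the real one included, gave as many genes (highest other 350). The count was 52 without BDL 3, 9 without BDL plus senkyunolide A library 1, 1 without BDL 1 and 0 without each of the other 6 libraries. The covariance of the log2 changes across genes was -0.139, against -0.041 in simulations where the groups differed only through the shared BDL libraries (lowest -0.045, highest -0.037). Noise was simulated independently for each gene, so this range leaves out the spread from genes that vary together. The difference of -0.098 ranged from -0.226 without BDL 3 to -0.017 without BDL plus senkyunolide A library 1, and was -0.022 without BDL 2 and -0.167 without BDL plus senkyunolide A library 3. The correlation across genes, which are not independent replicates, was -0.47 against -0.50 simulated, and 67.3% of genes had opposite signs against 66.7% simulated. With 3 BDL libraries no split leaves 2 in each part, so part of these values may come from the shared libraries.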

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

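The length-trend removal was a test chosen after the data were seen; the other settings were fixed before. In BDL against sham the count of genes, 1084, was 520 with no filter on low values, 678 with a mean FPKM of at least 5, 4039 with array weights, and 151 to 1763 with 1 library left out. Length-trend removal gave 502 higher and 482 lower genes. The lists called, 16, were 0 with an estimated correlation, 7 with fry and 12 to 17 with 1 library left out. In BDL plus senkyunolide A against BDL the count of genes, 1, was 3330 with array weights (1454 higher, 1876 lower), 0 with the 6 libraries alone, and 0 to 64 with 1 library left out; without a filter the 1 gene was Bex2, chosen after its values were seen, and not Gstm3. The lists called, 16, were 9 with a mean FPKM of at least 5, 10 with the length trend removed, 0 with an estimated correlation, 0 with fry and 10 to 16 with 1 library left out. In BDL plus senkyunolide A against sham the count of genes, 214, was 418 with a pseudocount of 0.1, 3 with no filter (Ces2b, Lrp2bp and Meig1, chosen after their values were seen), 133 with median-ratio scaling, 42 with quantile normalization and 307 with TPM rescaling. It was 5801 with array weights, 60 with the 6 libraries alone, 20 with the length trend removed and 0 to 1837 with 1 library left out. The lists called, 17, were 0 with an estimated correlation, 1 with fry and 14 to 19 with 1 library left out. Genes called in opposite directions, 1, were 1312 with array weights, 0 with the 6 libraries alone and 0 to 52 with 1 library left out. Myc in BDL plus senkyunolide A against sham took a negative value of -0.78 with array weights (limma adjusted p = 0.0063; 0.0063 to 0.996 over 21 alternatives), and Hdac3 passed there with the same weights (0.34, adjusted p = 0.00627). Myc also passed in BDL plus senkyunolide A against BDL with array weights (-0.92, adjusted p = 0.0376). Fewer libraries entered the left-out and 6-library settings, and the filter settings changed which genes were tested; what moved the counts was not tested. The fit of the array weights stopped before it converged, with weights from 0.205 for BDL plus senkyunolide A library 1 to 7.5 for library 2 of that group. Robust empirical Bayes has no form in camera and was not run for lists. Of the 55 named genes that passed in BDL against sham, 31 passed under the settings fixed before other than the left-out libraries. With each library left out in turn 19 passed. Some genes were not tested under every setting (Krt7 under 20 of 21), and a setting without the gene was not counted. Sign changes among named genes were found in Traf6 and Hdac3 (BDL plus senkyunolide A against BDL) and in Myc.

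The replicate numbers gave no clear sign of pairing. Deviations of libraries with the same number correlated at -0.39 to 0.25, and 1 of 9 libraries correlated best with its own number. With 3 libraries per group these values cannot exclude pairing, which was not tested further. With the replicate number as a block the counts of genes were 882, 0 and 374 in the 3 comparisons and 0 in opposite directions, and the lists called were 16, 18 and 19. Depth enters only as an estimate, and at log2 changes of 1 about 47% to 55% of simulated changes were recovered.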

Other observations

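The tests of hepatocyte RNA, of a swap or a sham library under another label, and of time of day were chosen after the result was seen, and the length test after the data were seen but before its own result; the splits were set before. Some members passed in limma in lists that camera did not call in BDL against sham. Of 22 immediate early and heat shock genes 8 rose and 2 fell (12 and 3 adjusted over the list alone). That list had a median of 0.77 (camera adjusted p = 0.104) and was called higher by fry (fry adjusted p = 0.0485). Of 27 unfolded protein response genes 4 rose (4 adjusted over the list alone), the stress transcription factor Atf3 (2.24 ± 0.35), the asparagine synthetase Asns (2.18 ± 0.36), the pseudokinase Trib3 (1.87 ± 0.41) and Sdf2l1 (1.10 ± 0.31) of the endoplasmic reticulum. The unfolded protein response list had a median of -0.07, a mean of 0.18 and a camera direction of down (adjusted p = 0.609). Of 20 YAP and TGF-beta response genes 5 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.75, camera adjusted p = 0.0567). Of 23 extracellular matrix genes 3 rose and 1 fell (3 and 3 adjusted over the list alone), with Mmp14 and Timp1 rising by 1.60 ± 0.30 and 2.25 ± 0.59 and Col14a1 falling by 1.62 ± 0.37. Their median was 0.25 and the camera direction down (adjusted p = 0.904). Of 18 cell cycle genes 1 rose, the replication licensing factor Cdt1 (1.31 ± 0.24; camera adjusted p = 0.88), and of 21 glycolysis genes 2 rose (2 rose and 1 fell adjusted over the list alone; mean 0.09, camera direction down, adjusted p = 0.758).

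Of 6 Notch and Hedgehog genes 0 passed in limma, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.536). Of 19 stellate cell markers 1 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.148). Of 7 erythroid markers 1 fell (median 0.30, mean -0.03, camera direction down, adjusted p = 0.88), and of 6 mesothelial markers 1 rose (adjusted p = 0.88). In BDL plus senkyunolide A against BDL camera called 9 further lists, with 0 members passing in limma over all genes and 0 of the lists called with an estimated correlation (adjusted p 0.73 to 0.84). Higher were the reactive cholangiocyte secretory (median 0.36, adjusted p = 0.00158), interferon (0.20, 0.00136), acute phase (0.47, 0.00637), mesothelial (0.52, 0.00999) and macrophage lists (0.28, 0.0303), and the ribosomal (0.14, 0.00107), hepatocyte (0.08, 0.0013) and oxidative phosphorylation lists (0.03, 0.0127). The lymphocyte list was lower (-0.51, 0.0482). In these 9 lists 0, 4, 4, 0, 0, 4, 10, 5 and 2 members had an unadjusted p under 0.05, in the order given, and adjusted over the list alone 2 hepatocyte markers were higher and 0 members of the others passed. TPM rescaling turned the medians of the ribosomal, hepatocyte and oxidative phosphorylation lists negative, and quantile normalization that of the hepatocyte list. Each call ended with some libraries left out. For BDL plus senkyunolide A library 1 these were the hepatocyte, ribosomal, oxidative phosphorylation and lymphocyte calls. For library 2 they were the reactive secretory, acute phase, macrophage and lymphocyte calls, and for library 3 the reactive secretory, interferon, acute phase, macrophage and mesothelial calls. BDL 1 ended the oxidative phosphorylation, macrophage and mesothelial calls, BDL 3 the oxidative phosphorylation, acute phase, macrophage, lymphocyte and ribosomal calls, and BDL 2, sham 1 and sham 2 the lymphocyte call. The macrophage list took the direction down without library 3 of BDL plus senkyunolide A. The highest adjusted p over 13 other settings was 0.146 (interferon) to 0.961 (hepatocyte).

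Hepatocyte transcripts led in libraries labelled cholangiocyte. At least 97.2% of the 36 hepatocyte markers were among the 1000 genes with the highest FPKM in each library, against 2 to 4 of the 34 biliary markers. Hepatocyte RNA in the material sequenced may account for this, but the count comes close to restating the pattern and adds little to it. How that material was isolated is not given. Expression brought on by ligation is argued against, since the lowest sham share exceeded the highest BDL share by 1.61 percentage points. The median FPKM of all listed biliary markers was 0.513 (sham 2) to 3.83 (BDL 3) over the 9 libraries. That of the hepatocyte markers was 1161 (BDL 2) to 2653 (BDL plus senkyunolide A library 1). Macrophage medians (6.43 to 36.3) and endothelial medians (2.36 to 7.47) also lay above the biliary median in each library. Neutrophil medians lay below it in each library, and stellate and erythroid medians above it in some. These values argue against libraries made up mostly of cholangiocyte RNA, so the changes found here cannot be assigned to cholangiocytes. The exact share of RNA from cholangiocytes was not measured.

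BDL plus senkyunolide A library 1 lay close to the sham libraries. A swap with a sham library is argued against, since each sham library correlated better with the other sham libraries than with libraries 2 and 3 of that group, by at least 0.073. A first test of a sham library under this label placed library 1 on the axis from sham to BDL. It lay at 0.39 over 1722 genes, and the left-out sham libraries at -0.08 to 0.44. Those sham values came from other gene sets, of 801 to 2531 genes, so the positions are not directly comparable. Over the same 1722 genes the sham libraries lay at -0.14 to 0.16, below library 1. There the sham libraries themselves set the axis, so neither comparison decides the question. After that was seen, another test took the share of genes raised in BDL that lay at least 1 log2 unit above both remaining sham libraries. That share was 6.94% to 11.5% in library 1, at most 3.99% in a left-out sham library and 26.7% to 59.7% in library 2 of its group. Among genes raised by more than 2 log2 units the share was 42.3% to 49.3% in library 1. There it was 0.901% to 9.21% in a left-out sham library and 90.8% to 92.2% in library 2. Library 1 thus exceeded the sham libraries in some genes raised by ligation. A sham library that held some BDL RNA would pass this test too, and the test was chosen after the first result. A sham library under this label therefore stays open. A length trend is argued against too, since with it removed the library still correlated better with sham, by 0.048. A partial ligation or an uneven response may account for it and was not tested.

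Clock genes differed between the BDL and sham libraries, mostly through BDL 1 and 2. Dbp, a clock output factor, read 30, 48.6 and 3.53 FPKM in the BDL libraries and 2.02, 0.437 and 0.354 in sham, and the clock activator Arntl 0.226, 0.231 and 1.05 against 1.69, 1.46 and 1.58; both were chosen after their values were seen. The median difference of 10 output genes was 1.65 and that of Arntl, Npas2, Clock and Cry1 was -0.88, which lie 2.53 apart. Against the sham mean the output genes lay at 2.17 and 2.37 in BDL 1 and 2 but 0.42 in BDL 3, near the 0.40 of sham 1. The other 4 genes lay at -1.12, -1.17 and -0.39 in the BDL libraries, against -0.30 in sham 1. In the BDL plus senkyunolide A libraries the output genes lay at 0.53, 0.46 and 0.57 and the other 4 at -0.53, -0.96 and -0.81, so the output genes of BDL 1 and 2 stood above that group too. Collection at different times of day may account for this; the labels used here give no time, and an effect of ligation on the clock stays open.

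Splits of the libraries were counted for each result. With 10 splits of 6 libraries the share cannot go under 0.05. In BDL against sham 1 of 10 splits gave as many genes (real 1084, highest other 0) and 2 of 10 as many lists (16, highest other 17). In BDL plus senkyunolide A against sham 1 of 10 gave as many genes (214, highest other 0) and 2 of 10 as many lists (17, highest other 17). In BDL plus senkyunolide A against BDL 3 of 10 gave as many genes (1, highest other 327) and 3 of 10 as many lists (16, highest other 17). The split with 327 genes set BDL 1, BDL 2 and BDL plus senkyunolide A library 1 against the rest, which points to a structure of the samples. An exchange of labels between BDL 3 and that library would give the same split. Against it, Gstm3 read 2153 FPKM in BDL 3 (761 and 1545 in BDL 1 and 2) and 210 in that library (148 and 116 in libraries 2 and 3), Gpx2 11.5 and 2.26, and Gstm1 5846 and 1775. These genes were named for the difference between the labelled groups, so the exchange stays open. For genes called in opposite directions 7 of 100 drawn splits gave as many (1, highest other 350), so chance is not excluded.

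The NRF2 and glutathione list lay below the BDL mean in each BDL plus senkyunolide A library, with median log2 differences of -0.60, -0.67 and -0.66. Its median was -0.65, -0.54 and -0.52 without BDL 1, 2 and 3, and -0.47 with the length trend removed.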
